A study of Rattus norvegicus with 13 samples.

How the data were processed

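The 13 samples were total RNA from primary rat cortical cultures: 3 of neurons, 4 of astrocytes, 3 of oligodendrocytes and 3 of microglia, each labelled with Cy3 and hybridized to its own Agilent rat miRNA array. The labels give 10 days in vitro for every sample, while the culture protocol has microglia collected at 7 days. Each array held 7000 miRNA spots and 672 negative control spots, with 938 probes for 350 miRNAs. Per the file headers, the authors used Agilent Feature Extraction 9.5.3.1, which gives each spot an intensity after background subtraction with spatial detrending and each miRNA a total intensity with a detection call, without scaling between arrays. The deposited series table holds log2 values of the total signal after quantile normalization over 350 miRNAs and 22 control entries, as its values show. Its scale and method are not stated in the labels, and it was used as an alternative only.

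Spots with an outlier call were dropped, the rest were averaged per probe, and probes were averaged per miRNA. Each array was divided by its 75th percentile over the 119 miRNAs detected on all 13 arrays. Values were floored at 0.38% of that percentile, which is -8.04 in log2, the median over arrays of the lowest detected signal, and taken to log2. The 268 miRNAs detected on at least 3 arrays, whatever the group, were tested; 69 were detected on none. A fold against a group with no detected array was computed against the mean over that group's arrays of the lowest detected log2 signal, floored in the same way, and is given as a lower bound. A fold over neurons is also given as a lower bound where 1 of the 3 neuron arrays detected the miRNA, with the floored values of the other 2. The number of arrays limits the precision.

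All arrays were fitted together in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, default prior), with Benjamini-Hochberg adjustment over the tested miRNAs and a threshold of 0.05. Fits were made for the 4 types, for each of the 6 pairs, and for each type against the mean of the other 3. A miRNA was called higher or lower in a type when all 3 pairwise differences passed and were at least 1 in log2. The slide could not be fitted as a term, since each type lay on 1 slide. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

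The comparisons, the 18 miRNA lists and the alternatives were written before the data were examined. The lists were neuron-associated, astrocyte-associated, oligodendrocyte-associated, microglia and myeloid-associated, Dlk1-Dio3 imprinted cluster, endothelial and mural, mesenchymal and fibroblast, choroid plexus and ciliated ependyma, muscle, erythroid, epithelial miR-200 family, miR-17-92 cluster and paralogs, let-7, miR-30, miR-15/16, miR-181, miR-23/27/24, and miR-221 with miR-222. They came from general knowledge, and some share members: miR-138 is in the neuron and oligodendrocyte lists, miR-23a in the astrocyte and oligodendrocyte lists, and miR-134 and miR-136 in the neuron and Dlk1-Dio3 lists. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over 60 tests. The 2 pairs that share a slide were tested in the same way over 30 tests, which was added after the data were seen.

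Named miRNAs followed a fixed rule. For each type these were the 12 called higher and the 8 called lower with the highest smallest pairwise difference, and every tested member of that type's list, with 4 of the Dlk1-Dio3 list for neurons. For each pair they were the 3 with the highest difference in each direction and no overlap between arrays, which chance gives in 10% of cases with 3 against 3 arrays. For every other list they were the 2 members with the highest difference. miR-370 and miR-409-3p in neurons, miR-211 in astrocytes, miR-872*, miR-193 and miR-503 in oligodendrocytes, and the levels on single arrays were named after their values were seen.

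Alternatives were normexp background correction (offset 50), the 75th percentile over all miRNAs, quantile normalization, no scaling, the gene-level total signal, the brightest probe, the deposited table, no filter and a filter of detection on all arrays, a 5th percentile floor, eBayes with trend and robust, fits of only the groups compared, the replicate number as a block, and leaving out each array in turn. Leaving out oligodendrocyte array 2 with astrocyte array 3 was chosen after seeing the data. The steps were tested on simulated data with 30 changes of each size per type among 268 miRNAs. The changed miRNAs were drawn from the brighter ones, up and down in equal number, and in 1 type at a time. Changes of 1.5 in log2 were recovered in 83.3% of cases for neurons, 76.7% for astrocytes, 86.7% for oligodendrocytes and 93.3% for microglia, and changes of 3 in 100%, 100%, 100% and 96.7%. Of 202 unchanged miRNAs, 0 were called by limma as higher or lower in a type, and 2.64% to 2.97% were called per pair at an adjusted p under 0.05. A shifted list was called in each type, and 0 of 14 other lists were. These rates may not hold for miRNAs near the floor or where most miRNAs differ, as they do on the real arrays. Positions are those in the files, in build rn4. Targets of the miRNAs, other control probes and pixel-level values were not analysed here.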

Results

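MicroRNA (miRNA) levels were measured in 4 kinds of primary culture made from the cortex of rats at postnatal day 1: neurons (n = 3 arrays), astrocytes (n = 4), oligodendrocytes (n = 3) and microglia (n = 3). Neurons were grown with cytosine arabinoside, which kills dividing cells, and astrocytes were grown in horse serum and shaken to remove other cells. Oligodendrocytes and microglia came from the supernatant of mixed cultures. Each of the 13 arrays received 100 ng of total RNA and carried probes for 350 rat miRNAs, whose names are given here without the prefix rno-. The summed miRNA intensity was 276541 to 514312 on the neuron arrays, 147231 to 300388 on the astrocyte arrays, 107778 to 185769 on the oligodendrocyte arrays and 128680 to 160559 on the microglia arrays. Neuron arrays detected 241 to 258 miRNAs, astrocyte arrays 160 to 208, oligodendrocyte arrays 193 to 201 and microglia arrays 160 to 176. On at least 3 arrays 268 miRNAs were detected, and these were tested. Levels are log2 signal relative to the array's own 75th percentile, with mean ± SD over arrays. Values were floored at -8.04, the median over arrays of the lowest detected level, which on single arrays ran up to -6.79 (microglia array 3). A fold against a group with no detected array is a lower bound, and a fold against a group with 1 detected array rests on values near the floor.

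The question was which miRNAs mark each of the 4 cell types. Of the 268 tested miRNAs, 256 differed among the types (limma F test, adjusted p under 0.05), as did 117 of the 119 detected on all arrays. The brain-enriched miR-9 ranged from 4.22 ± 0.05 in neurons (n = 3) to -5.41 ± 0.07 in microglia (n = 3). The immune regulator miR-146a ranged the other way, from -7.64 ± 0.24 in neurons to 3.99 ± 0.15 in microglia. Higher in a type than in each of the other 3, by at least 2-fold, were 73 miRNAs for neurons, 34 for microglia, 13 for oligodendrocytes and 9 for astrocytes. Lower than in each other type were 42 for microglia, 20 for neurons, 9 for oligodendrocytes and 8 for astrocytes. These calls compare floored values, so for dim miRNAs not detected in microglia the lower bound can fall short of 2-fold. Arrays of 1 type correlated at a median r of 0.998 in neurons, 0.997 in astrocytes, 0.984 in oligodendrocytes and 0.974 in microglia, across miRNAs. Between types the median r ran from 0.439 for neurons with microglia to 0.909 for astrocytes with oligodendrocytes. The p-values measure the spread between samples, which the study's text calls biological replicates. Neurons and oligodendrocytes lay on slide 1 and astrocytes and microglia on slide 2, so in every other pair the slide and the cell type cannot be told apart.

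**Figure D1:**
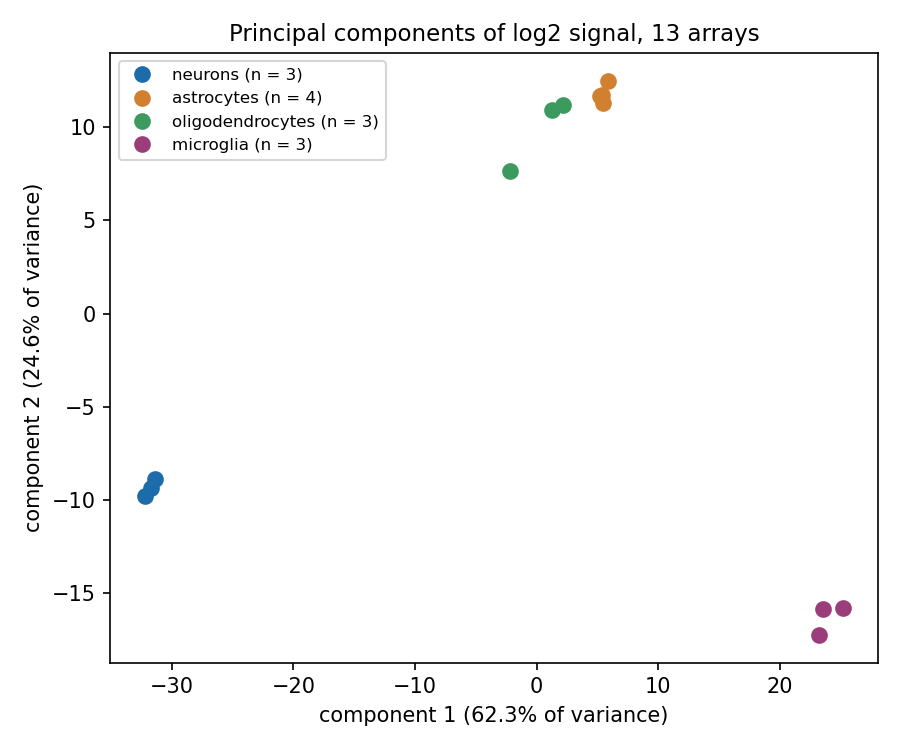
Principal components 1 and 2 of the log2 signal of the tested miRNAs, in arbitrary component units, with each point an array coloured by cell type (n = 3, 4, 3 and 3). Component 1 held 62.3% and component 2 held 24.6% of the variance, and the arrays of each type lay together, with oligodendrocyte array 2 nearest the neurons among its group.

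Neurons were marked by the miRNAs of the imprinted Dlk1-Dio3 domain and by miR-124 and miR-128, which promote neuronal differentiation and synaptic function. miR-434 of this domain stood at 0.75 ± 0.08 in neurons (n = 3) and was 149-fold above oligodendrocytes, the closest type (log2 7.22 ± 0.415 SE, adjusted p = 2.84e-08). miR-376a was 115-fold above oligodendrocytes, where 1 of 3 arrays detected it, miR-127 was 93.8-fold and miR-136 68.8-fold above them (110-fold without oligodendrocyte array 2). miR-410, detected on 3 of 3 neuron arrays and on no other array, was at least 79.2-fold higher than in oligodendrocytes. miR-329, miR-323, miR-495, miR-136*, miR-379, miR-382 and miR-433, from the same domain, were also higher than in each other type, and none of them was detected outside neurons. miR-124 was 3.13 ± 0.19 in neurons and 12.3-fold above oligodendrocytes (log2 3.62 ± 0.575 SE, adjusted p = 0.000132), and at least 1076-fold above microglia. The first fold was 22-fold without oligodendrocyte array 2 and 7.97-fold without array 1. miR-128 was 22.5-fold above oligodendrocytes (adjusted p = 7e-08), and miR-132, which responds to neuronal activity, was 15.7-fold above astrocytes (adjusted p = 0.00048).

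The 41 tested members of the Dlk1-Dio3 list, fixed before the data were examined like every list here, map to chromosome 6 from 134176812 to 134425147 in build rn4, a span of 248 kb. Of these 41, 40 rose over the mean of the other types (40 adjusted over the list alone), none fell, and miR-409-3p did not pass (adjusted p = 0.134). The list shifted as a set (camera, adjusted p = 8.42e-11; adjusted p = 0.0811 with an estimated correlation), and 37 members were higher than in each other type. Not higher than in each were miR-134, miR-370, miR-409-3p and miR-494. The other 36 miRNAs called higher in neurons lay outside this list, and 37 of the 73 were detected on no array of another type, 30 of them in the domain. Those 30 passed the filter through the neuron arrays alone and could hardly do other than rise there. The counts and the set call of this list were thus largely fixed by the filter, which left 41 of its 48 members on the array. In return the list lay below a mean that includes neurons in astrocytes (40 of 41 members), oligodendrocytes (36) and microglia (35). The set calls had adjusted p = 4.53e-11, 1.78e-06 and 4.12e-06 (camera), and 0.0811, 0.173 and 0.173 with an estimated correlation. Most members lay at or near the floor in all 3 types, so these values restate the neuron level and show no decrease. Within slide 2 the list was not called between astrocytes and microglia (0 members higher in astrocytes, 3 in microglia, camera adjusted p = 0.751). The call in microglia was lost under another background correction, normexp (adjusted p = 0.278, median 0.04 in place of -1.12). Without any 1 of the neuron arrays 10 members were tested, and the calls were lost in oligodendrocytes (adjusted p = 0.3, 0.288 and 0.285 without arrays 1, 2 and 3, medians -0.79, -0.85 and -0.84 in place of -1.20) and microglia (0.0984, 0.0964 and 0.092, medians -2.32, -2.35 and -2.36).

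**Figure D2:**
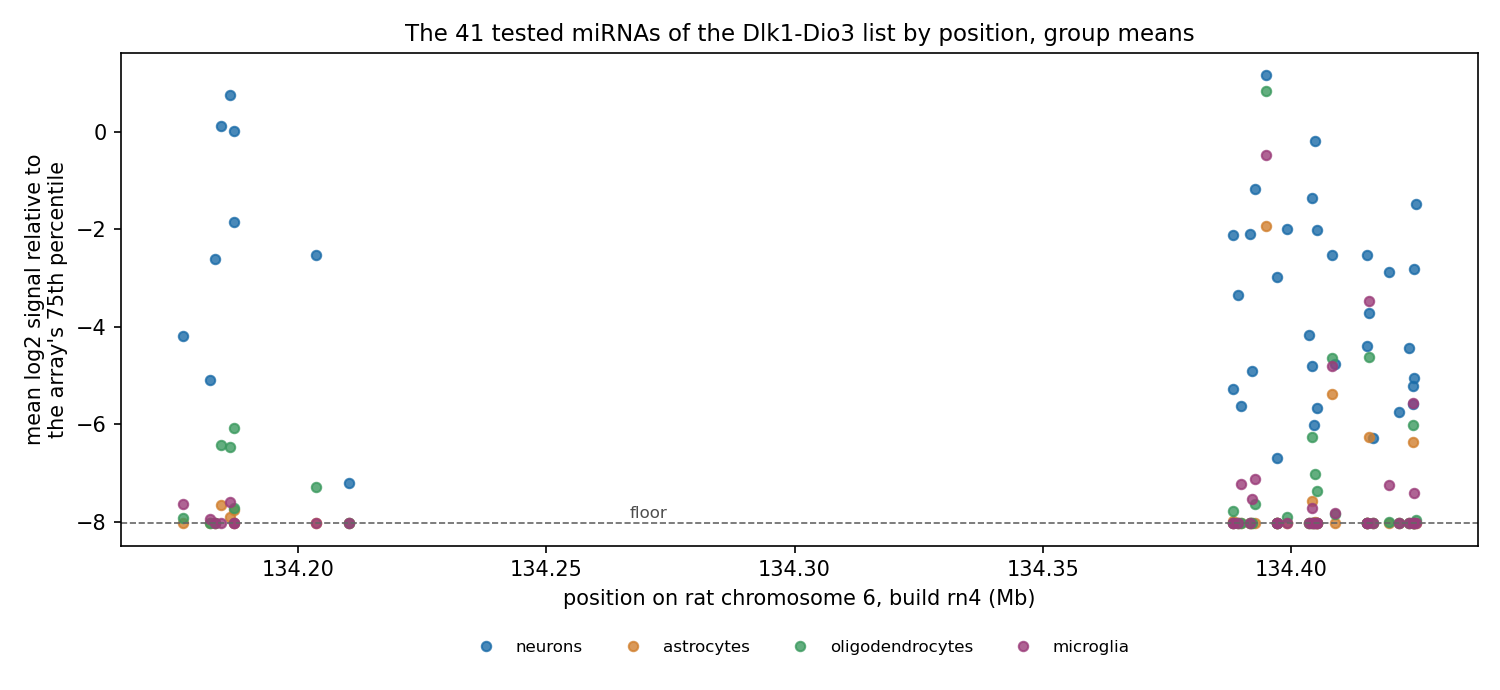
Mean log2 signal relative to the array's 75th percentile (y axis) of the 41 tested Dlk1-Dio3 miRNAs by position on rat chromosome 6, build rn4, in Mb (x axis). Each point is the mean of a cell type (3 or 4 arrays), the dashed line is the floor at -8.04, and miR-494 at 1.16 in neurons was also bright in oligodendrocytes at 0.84.

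Of the 17 tested neuron-associated miRNAs, 16 rose in neurons (16 adjusted over the list alone) and 12 were higher than in each other type (camera, adjusted p = 0.00676; adjusted p = 0.36 with an estimated correlation). Besides miR-124, miR-128, miR-132 and miR-136 these were miR-129, miR-129*, miR-137, miR-139-5p, miR-153, miR-218, miR-7a and miR-7b. miR-137, a brake on neural progenitor division, was 8.42-fold above oligodendrocytes (adjusted p = 4.3e-05; 13.1-fold without oligodendrocyte array 2), and miR-129* was 7.53-fold above them (adjusted p = 5.49e-06). miR-9 exceeded astrocytes by 1.65-fold and miR-9* exceeded oligodendrocytes by 1.82-fold, both under the 2-fold limit. miR-138 was higher in oligodendrocytes than in neurons (log2 neurons minus oligodendrocytes -0.65 ± 0.21 SE, adjusted p = 0.0146). miR-212, made from the same transcript as miR-132, did not differ from the mean of the others (log2 -0.05, adjusted p = 0.718). miR-134 rose over that mean (log2 1.07, adjusted p = 0.000396), but the difference was -0.05 under quantile normalization and -0.12 in the deposited table.

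Neurons were low in the growth-promoting miR-17-92 cluster and its paralogs: 14 of 14 fell (14 adjusted over the list alone), 9 of them lower than in each other type (camera, adjusted p = 7.99e-08; adjusted p = 0.185 with an estimated correlation). miR-18a was 7.32-fold, miR-20a 5.62-fold and miR-17-5p 5.58-fold below astrocytes, the closest type (adjusted p = 2.63e-08, 1.19e-08 and 1.34e-08). The myeloid miRNAs miR-146a and miR-142-3p, each detected on 1 of 3 neuron arrays, were at least 92.2-fold and at least 57.3-fold below oligodendrocytes. miR-223 was 9.8-fold and miR-142-5p at least 12.4-fold below them. miR-21, raised in reactive and dividing cells, was 6.83-fold below oligodendrocytes (adjusted p = 3.23e-06). Of the 8 tested myeloid miRNAs, 6 fell and 2 rose (6 and 2 adjusted over the list alone; camera, adjusted p = 0.00623; adjusted p = 0.255 with an estimated correlation). Leaving out any neuron array gave 33 to 39 miRNAs higher in neurons in place of 73, since a miRNA seen on neuron arrays alone then misses the limit of 3 arrays, and normexp gave 32 higher and 13 lower. With the 75th percentile over all miRNAs 37 were lower in neurons and with quantile normalization 47, and 43 were higher in the deposited table.

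Astrocytes were marked by few miRNAs, chief among them miR-449a, a regulator of multiciliated cell formation, at 0.34 ± 0.14 (n = 4). It was 16.7-fold above neurons, the closest type (log2 4.06 ± 0.212 SE, adjusted p = 9.55e-09), and at least 203-fold above oligodendrocytes. Its relatives miR-34b and miR-34c were 3.48-fold and 3.03-fold above neurons (adjusted p = 1.17e-08 and 5.64e-06). miR-31 and miR-143, which is abundant in smooth muscle and other mural cells, were detected on 4 of 4 astrocyte arrays and on no other, at least 13.2-fold and at least 12.3-fold above neurons. miR-193 was 3.26-fold above microglia (adjusted p = 0.000403). miR-224, miR-375 and miR-203 were also higher, near the floor: miR-224 and miR-375 were at least 4.49-fold and at least 2.8-fold above neurons, and miR-203 was at least 2.44-fold above them, with 1 of 3 neuron arrays detecting it. The microglia arrays detected only down to -7.67, -6.93 and -6.79. Bounds over microglia are therefore smaller than those over neurons for miR-31, miR-143, miR-224 and miR-375. Lower than in each other type were miR-327 (at least 6.65-fold below microglia), miR-188 (4.87-fold below microglia, adjusted p = 5.88e-05), miR-466b, miR-7a, miR-134, miR-494, miR-139-3p and miR-423.

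Of the 11 astrocyte-associated miRNAs, 10 rose over the mean of the other types (10 adjusted over the list alone; camera, adjusted p = 0.000153; adjusted p = 0.0811 with an estimated correlation), and none was 2-fold above each other type. miR-21 rose most over that mean (log2 2.34 ± 0.208 SE), though it was 1.57-fold lower than in microglia (adjusted p = 0.0492). miR-29a and miR-29b, which repress collagen genes, exceeded neurons by 1.42-fold and 1.68-fold (adjusted p = 0.00045 and 0.000988), and miR-29c was 1.56-fold below neurons. miR-125b-5p was 2.59-fold and miR-26a 1.76-fold below neurons, and miR-26a did not differ from the mean of the others (adjusted p = 0.165). miR-23a, miR-24 and miR-27a lay 1.69-fold, 1.42-fold and 1.7-fold below microglia, while miR-23b and miR-27b did not differ from oligodendrocytes (adjusted p = 0.737 and 0.126). Within slide 2 the astrocyte list was not called against microglia (6 members higher in astrocytes, 3 in microglia, camera adjusted p = 0.568). The choroid plexus and ciliated ependyma list rose in 4 of 5 members (4 adjusted over the list alone; adjusted p = 0.00626; adjusted p = 0.0811 with an estimated correlation), miR-204 among them and miR-211 not (adjusted p = 0.665). The miR-23/27/24 clusters, which share 5 members with the astrocyte list, rose in 6 of 6 (adjusted p = 0.00626; adjusted p = 0.0811 with an estimated correlation), a call lost without scaling (adjusted p = 0.0693, median 0.74 in place of 0.58). Under normexp 2 miRNAs were higher and 2 lower than in each other type, with miR-224, miR-375, miR-203 and miR-423 no longer different from the mean of the others, and 5 were lower in the deposited table.

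The astrocyte arrays also gave signal for the myeloid miRNAs: miR-146a was -0.08 ± 0.03 (n = 4), miR-142-3p -1.06 ± 0.01 and miR-223 -1.34 ± 0.10. These levels were at least 188-fold (miR-146a) and at least 99-fold (miR-142-3p) above neurons, where 1 of 3 arrays detected each (adjusted p = 7.28e-10 and 2.3e-10). They were between 5.94% and 7.38% of the microglial level for miR-146a, miR-142-3p, miR-142-5p and miR-223.

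Oligodendrocytes were marked by miR-219-5p, miR-219-2-3p and miR-338, which drive the differentiation of oligodendrocyte precursors. miR-219-5p was 1.88 ± 0.26 (n = 3), 5.77-fold above astrocytes, the closest type (log2 2.53 ± 0.263 SE, adjusted p = 1.13e-05), and 71.1-fold above microglia. miR-219-2-3p was 5.38-fold above astrocytes and at least 110-fold above neurons, where 1 of 3 arrays detected it (adjusted p = 1.82e-05 and 2.06e-09). miR-338 was 3.24-fold and miR-338* 5.3-fold above astrocytes (adjusted p = 3.41e-05 and 2.76e-05). Of 7 tested miRNAs on chromosome X (rn4, 139995000 to 140000232), which were grouped after their calls were seen and not tested as a set, 6 were also called higher: miR-322, miR-322*, miR-351, miR-450a, miR-542-3p and miR-542-5p. Their folds over the closest type ran from 2.13-fold (miR-450a over microglia) to 3.56-fold (miR-322* over neurons), and miR-351 moved from 2.85-fold to 4.99-fold over microglia without microglia array 3. The other, miR-503, exceeded microglia by 0.74 log2 (adjusted p = 0.0113), under the 2-fold limit. miR-346, miR-181b and miR-872* completed the 13. miR-222 and miR-221, which target the cell cycle inhibitor p27Kip1, were 5.58-fold and 3.54-fold below neurons, the closest type (adjusted p = 3.45e-05 and 0.00107), with miR-222 detected on 1 of 3 oligodendrocyte arrays, and both members of that cluster fell. miR-449a, miR-152, miR-210, miR-34a, miR-29b, miR-29c and miR-193 were also lower than in each other type.

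Of the 7 tested oligodendrocyte-associated miRNAs, 6 rose and miR-23a fell (6 and 1 adjusted over the list alone), with 4 higher than in each other type (camera, adjusted p = 0.00374; adjusted p = 0.0811 with an estimated correlation). miR-138 was 1.57-fold above neurons, and miR-32 did not differ from microglia (adjusted p = 0.0517). The list fell in neurons in 6 of 7 members (adjusted p = 0.0217; adjusted p = 0.138 with an estimated correlation), a call lost under 3 other scalings, with adjusted p = 0.131 for the 75th percentile over all miRNAs, 0.117 for quantile normalization and 0.0994 in the deposited table, where the medians were -2.10, -1.76 and -1.71 in place of -1.04. The miR-181 family rose in 4 of 4 (4 adjusted over the list alone, camera adjusted p = 0.0162, and 0.185 with an estimated correlation), led by miR-181b, the only member higher than in each other type. The family median was 1.03 here and 1.43 in neurons, against means lowered by microglia (median -2.05 there). The miR-17-92 list rose in 10 of 14 (10 adjusted over the list alone; adjusted p = 2.44e-05; adjusted p = 0.259 with an estimated correlation), but against a mean lowered by neurons (median -1.93 there), and 0 of its members were higher than in each other type. Its median was 1.23 here and 0.87 in microglia. The neuron-associated list rose in 9 of 17 members and fell in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.0178; adjusted p = 0.411 with an estimated correlation), but not without oligodendrocyte array 2 (adjusted p = 0.0516, median 0.09) or under normexp (adjusted p = 0.194, median -0.18 in place of 0.29). Array 2 held more miR-124 than arrays 1 and 3 (1.21 against -1.72 and -0.94) and more miR-146a (-0.19 against -1.79 and -1.36). Normexp left 5 miRNAs higher and 3 lower than in each other type, with miR-338*, miR-346, miR-351 and miR-152 no longer different from the mean of the others, and 2 were lower with the 75th percentile over all miRNAs and 3 in the deposited table.

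Microglia were marked by miR-150, miR-146a, miR-142-3p, miR-142-5p and miR-223, which act in blood-derived immune cells. miR-150 was 0.52 ± 0.58 (n = 3), 114-fold above astrocytes (log2 6.83 ± 0.208 SE, adjusted p = 1.48e-10) and at least 318-fold above oligodendrocytes, where it was not detected. miR-146a was 16.8-fold above astrocytes and at least 3158-fold above neurons, where 1 of 3 arrays detected it (adjusted p = 2.57e-07 and 1.78e-11). miR-142-5p, miR-142-3p and miR-223 were 16.4-fold, 13.4-fold and 13-fold above astrocytes. The epithelial miR-200c and miR-141, neighbours on chromosome 4, were detected on 3 of 3 microglia arrays and on no other, at least 24.9-fold and at least 12.5-fold above neurons. miR-126, known from endothelium, was 6.35-fold above neurons (adjusted p = 1.34e-07), and miR-378*, miR-138*, miR-877 and miR-532-3p were also higher than in each other type. miR-9 was 395-fold below oligodendrocytes (adjusted p = 4.49e-16) and miR-9* 50.4-fold below astrocytes. miR-129*, miR-384-5p, miR-153, miR-129, miR-325-3p and miR-138 were detected on no microglia array, and miR-129* was at least 72.7-fold below astrocytes.

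**Figure D3:**
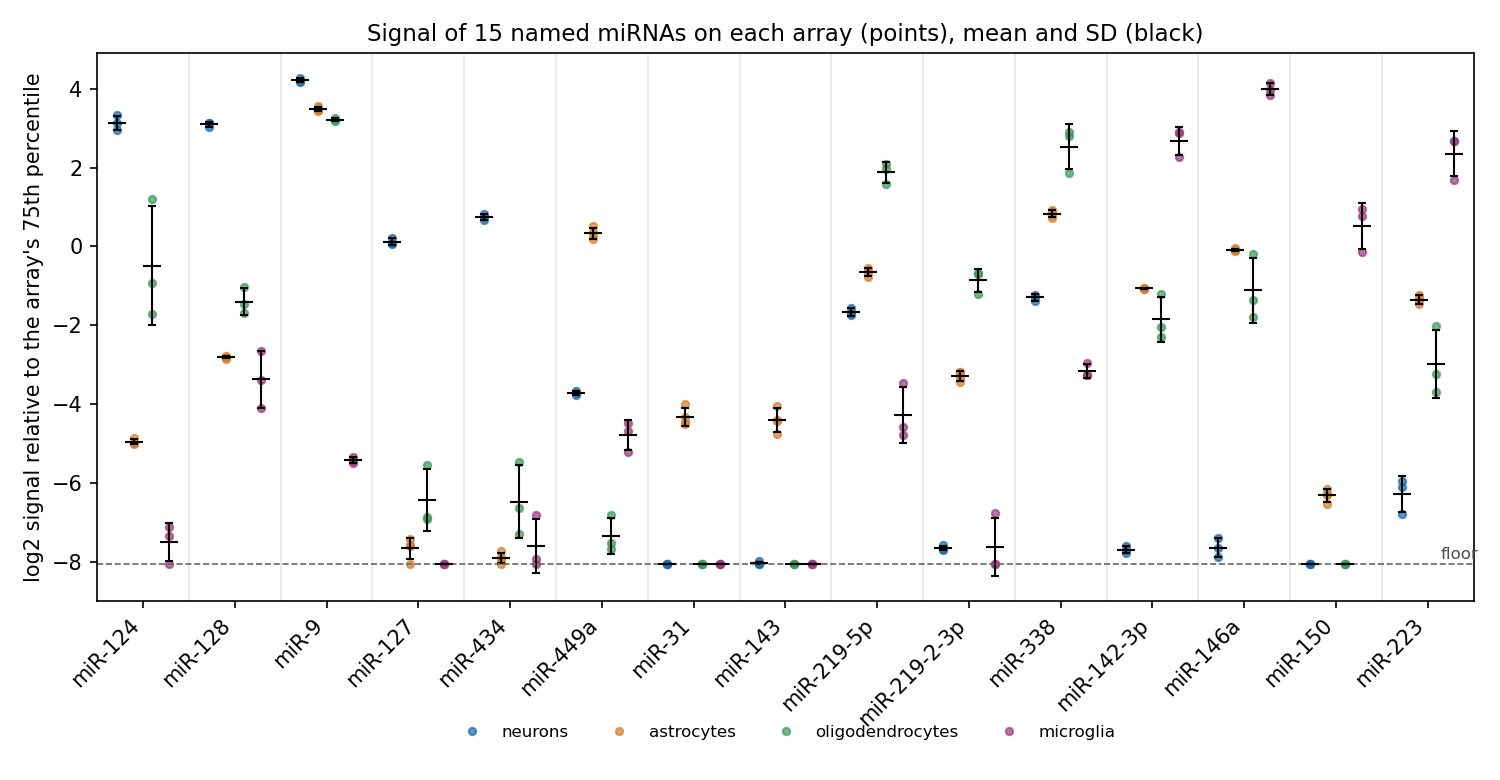
Log2 signal relative to the array's 75th percentile (y axis) of 15 named miRNAs (x axis) on each array, coloured by cell type, with black bars for the mean and SD of 3 or 4 arrays and a dashed line at the floor of -8.04. miR-9 stood at 4.22 in neurons, 3.49 in astrocytes, 3.21 in oligodendrocytes and -5.41 in microglia, and miR-146a at -7.64, -0.08, -1.11 and 3.99.

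All 8 tested myeloid miRNAs rose in microglia (8 adjusted over the list alone), 6 of them higher than in each other type (camera, adjusted p = 0.000106; adjusted p = 0.138 with an estimated correlation). miR-146b was 2.12-fold above astrocytes, while miR-342-3p and miR-342-5p exceeded neurons by 1.8-fold and 1.63-fold. The let-7 family, which restrains growth and pluripotency genes, fell in 8 of 8 members (8 adjusted over the list alone; adjusted p = 0.0214; adjusted p = 0.312 with an estimated correlation), with let-7b at log2 -3.70 ± 0.0782 SE and let-7e at -3.31 ± 0.196 SE against the mean of the others. The set call for let-7 was lost with the 75th percentile over all miRNAs (adjusted p = 0.149, median -0.36 in place of -0.90) and without scaling (adjusted p = 0.111, median -1.63). The neuron-associated list fell in 14 of 17 and rose in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.0147; adjusted p = 0.402 with an estimated correlation). The miR-17-92 list rose in 14 of 14 (14 adjusted over the list alone; adjusted p = 0.000396; adjusted p = 0.315 with an estimated correlation), against a mean that includes the low neurons. Only 1 member was higher than in each other type, and within slide 2 the list was not called against astrocytes (adjusted p = 0.0694). Under normexp 21 miRNAs were higher and 15 lower than in each other type, and without scaling 21 were higher.

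Neurons and oligodendrocytes, compared within slide 1, differed in 209 of 268 miRNAs, with 156 higher in neurons and 53 in oligodendrocytes. miR-434, miR-376a and miR-127 stood higher in neurons, and miR-219-2-3p, miR-146a (at least 92.2-fold, adjusted p = 5.82e-09) and miR-142-3p (at least 57.3-fold, adjusted p = 1.76e-09) in oligodendrocytes. The levels of miR-146a, miR-142-3p, miR-142-5p and miR-223 on the oligodendrocyte arrays were 2.68% to 5.55% of those in microglia, and whether RNA from microglia accounts for them was not tested for the group as a whole. On this slide 39 of 41 Dlk1-Dio3 miRNAs were higher in neurons (camera, adjusted p = 7.48e-09, and 0.232 with an estimated correlation). Most of the 41 were tested only because the neuron arrays detected them. In oligodendrocytes 14 of 14 miR-17-92 miRNAs were higher (adjusted p = 1.45e-10, and 0.0861 with an estimated correlation). The oligodendrocyte-associated list was higher in oligodendrocytes in 6 of 7 (adjusted p = 0.00154; 0.181 with an estimated correlation), and the neuron-associated list in neurons in 15 of 17 without a set call (adjusted p = 0.2). The share of calls higher in neurons was 74.6%, and 45% with the 75th percentile over all miRNAs, 49.8% with quantile normalization and 49.3% in the deposited table, which moved the median difference of all miRNAs by -0.86, -0.79 and -0.86 log2. Normexp left 133 calls.

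Astrocytes and microglia, compared within slide 2, differed in 176 miRNAs, with 80 higher in astrocytes and 96 in microglia. miR-9 was 480-fold higher in astrocytes (log2 8.91 ± 0.0575 SE, adjusted p = 1.59e-16), and miR-135a and miR-129* were at least 86.3-fold and at least 72.7-fold higher. miR-150 (114-fold), miR-200c (at least 23.4-fold) and miR-130b (24.5-fold, adjusted p = 8.61e-07, detected on 1 of 4 astrocyte arrays) led in microglia. All 8 myeloid miRNAs were higher in microglia (adjusted p = 0.000373; 0.112 with an estimated correlation), as were 6 of 6 miR-30 miRNAs (adjusted p = 0.0131; 0.2 with an estimated correlation). All 8 let-7 miRNAs were higher in astrocytes (adjusted p = 0.00154; 0.181 with an estimated correlation), as were 9 of 17 neuron-associated miRNAs against 3 lower (adjusted p = 0.0345; 0.349 with an estimated correlation). Sets not called on this slide included the astrocyte list (camera, adjusted p = 0.568) and the choroid plexus and ciliated ependyma list (4 of 5 higher in astrocytes, 0.056). The miR-23/27/24 clusters were not called either (2 higher in astrocytes, 4 in microglia, 0.34). The share of calls higher in astrocytes was 45.5%, but 25.3% under normexp and 67.6% without scaling, with the median of all miRNAs moved by -0.37 and 0.11 log2.

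The miRNAs named for each pair had no overlap between the arrays of its types. Across slides, neurons differed from astrocytes in 218 miRNAs (150 higher in neurons, 68 in astrocytes). miR-124 was 272-fold higher in neurons (log2 8.09 ± 0.538 SE, adjusted p = 7.9e-08) and miR-434 and miR-376a at least 377-fold and at least 213-fold, while miR-21 was 37.4-fold higher in astrocytes (adjusted p = 7e-09). Neurons differed from microglia in 223 (140 higher in neurons, 83 in microglia), with miR-9 793-fold and miR-129* at least 735-fold higher in neurons, and miR-142-3p, detected on 1 of 3 neuron arrays, at least 1322-fold and miR-223 395-fold higher in microglia. The share higher in neurons over astrocytes was 68.8%, and 41.9%, 42.7% and 42.6% under those 3 scalings, whose medians moved by -0.82, -0.83 and -0.83 log2. Over microglia it was 62.8%, against 44.7%, 48.7% and 48.2% (median shifts -0.96, -0.81 and -0.73 log2), 40.8% under normexp, 78.2% without scaling and 52% among miRNAs detected on all arrays.

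Astrocytes differed from oligodendrocytes in 151 miRNAs (69 higher in astrocytes, 82 in oligodendrocytes). miR-449a, miR-135a (16.4-fold, adjusted p = 1.72e-07) and miR-222 (14.6-fold, adjusted p = 1.65e-06, 1 of 3 oligodendrocyte arrays detecting it) led in astrocytes, and miR-327 (at least 27.8-fold), miR-124 (22.2-fold, adjusted p = 2.95e-05) and miR-551b (at least 7.56-fold) in oligodendrocytes. Without oligodendrocyte array 2 miR-327 was at least 15.5-fold and miR-124 12.3-fold higher, and miR-124 was 34.1-fold higher without array 1. Normexp left 81 calls, without miR-551b, and no scaling left 100. Oligodendrocytes differed from microglia in 165 (86 higher in oligodendrocytes, 79 in microglia). miR-9 (395-fold), miR-129* (at least 97.6-fold) and miR-124 (at least 87.8-fold) led in oligodendrocytes, and miR-150, miR-223 (40.4-fold, adjusted p = 3.81e-07) and miR-126 (at least 33.8-fold) in microglia. For miR-124 the bound was 48.9-fold without oligodendrocyte array 2 and 135-fold without array 1. The share higher in oligodendrocytes was 52.1%, but 32.2% under normexp and 65.1% without scaling, with median shifts of -0.36 and 0.27 log2.

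Other families moved as well. let-7 rose in astrocytes in 6 of 8 members (6 adjusted over the list alone, camera adjusted p = 0.00676, and 0.258 with an estimated correlation), with let-7b 1.44 ± 0.0713 SE over the mean. That mean includes microglia, where let-7 was low (median -0.90), as does the mean for neurons. In astrocytes 0 members were higher than in each other type. The set call was lost under quantile normalization (0.0728), without scaling (0.0596) and in the deposited table (0.0518), with medians of 0.30, 0.45 and 0.30 in place of 0.29. All 8 let-7 and all 6 miR-30 members rose in neurons, where neither set passed (adjusted p = 0.0883 and 0.288) and where the 75th percentile over all miRNAs turned their medians to -0.26 and -0.34. The let-7 set did pass in neurons under normexp (0.00186), with no filter on detection (0.0283), among miRNAs detected on all arrays (0.026) and without neuron arrays 1, 2 and 3 (0.013, 0.0343 and 0.0305), at medians of 0.80, 0.80, 0.80, 0.86, 0.77 and 0.75 beside 0.80. miR-30 fell in 6 of 6 members in astrocytes and in oligodendrocytes without a set call (adjusted p = 0.0765 in each, medians -0.66 and -0.79). These sets were called under normexp (0.0297 and 0.0305, medians -0.61 and -0.71), with no filter on detection (0.0305 and 0.0283, medians unchanged) and without neuron arrays 1, 2 and 3 (0.0251, 0.0296 and 0.0284 in astrocytes, 0.0322, 0.0343 and 0.0335 in oligodendrocytes). Among miRNAs detected on all arrays the astrocyte set was called (0.026, median -0.69). miR-30 rose in microglia in 6 of 6 (adjusted p = 0.0162; adjusted p = 0.258 with an estimated correlation), with miR-30d 1.14 ± 0.145 SE and miR-30b-3p 1.09 ± 0.133 SE over the mean. The miR-23/27/24 clusters fell in neurons in 6 of 6 (adjusted p = 0.00161; adjusted p = 0.0811 with an estimated correlation) and rose in microglia in 4 of 6 (adjusted p = 0.0214; adjusted p = 0.138 with an estimated correlation), led by miR-27a and miR-23a. Both microglia calls were lost under normexp (0.0842 for miR-30, 0.0815 for miR-23/27/24), quantile normalization (0.0503, 0.0689), no scaling (0.273, 0.111) and the deposited table (0.0532, 0.0547). In that order the medians were 0.61, 0.88, 0.15 and 0.70 for miR-30 in place of 0.87, and 0.89, 1.66, 0.47 and 1.37 for miR-23/27/24 in place of 1.20. On slide 1 the miR-23/27/24 medians were -0.99 in neurons and -0.91 in oligodendrocytes. On slide 2 they were 0.58 in astrocytes and 1.20 in microglia. Within slide 1 the clusters were not called between the 2 types (1 member higher in neurons, 2 in oligodendrocytes, camera adjusted p = 0.219). Their decrease in neurons therefore cannot be told apart from the slide.

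The miR-200 list was called lower in neurons in 2 of 3 members (adjusted p = 0.0385; adjusted p = 0.173 with an estimated correlation), but against a mean that includes microglia, the only type in which these 2, miR-200c and miR-141, were detected. The median of -1.22 was the same in astrocytes and oligodendrocytes, so it restates the microglial level and shows no decrease of neurons. The call was also lost without oligodendrocyte array 2 (adjusted p = 0.0512), neuron array 1 (0.0715) or neuron array 3 (0.0646), with medians of -1.23, -1.16 and -1.16. It was lost with the 75th percentile over all miRNAs (0.149), quantile normalization (0.1), no scaling (0.0589) and the deposited table (0.168), at medians of -1.26, -1.42, -1.07 and -1.18, and under normexp (0.261), where the median shrank to -0.48. In microglia 2 of 3 rose without a set call (adjusted p = 0.105), and the set was called without scaling (0.024, median 3.22 in place of 3.65). In microglia the 4 miR-181 miRNAs fell, miR-181c and miR-181d most, without a set call (adjusted p = 0.0975, median -2.05). The set was called under normexp (0.00664, median -1.09), with no filter (0.0476, -2.05), among miRNAs detected on all arrays (0.0359, -2.05) and without neuron arrays 1, 2 and 3 (0.0453, 0.0459 and 0.0488, medians -2.02, -2.07 and -2.05). In the miR-15/16 family miR-195 rose in neurons (log2 2.09 ± 0.195 SE) and miR-497 fell in microglia (-4.30 ± 0.312 SE), with no set call in any type (adjusted p = 0.297 in neurons). The mesenchymal list had no set call either (adjusted p = 0.483 in neurons), with miR-199a-3p lower (-2.77 ± 0.292 SE) and miR-214 higher (2.53 ± 0.258 SE) in neurons. All 3 tested muscle miRNAs rose in neurons without a set call (adjusted p = 0.297), miR-133b by 2.03 ± 0.256 SE, though normexp turned their median to -0.08. The endothelial and mural list, the erythroid list and the pair of miR-221 with miR-222 had too few tested members for a set test: miR-126 rose in microglia and less in neurons (4.15 and 0.59), and miR-143 rose in astrocytes. miR-221 and miR-222 rose in astrocytes (1.80 and 1.94) and in microglia (2.11 and 1.18), and miR-451 rose in neurons (2.62 ± 0.175 SE) and in microglia (1.19). Of 60 set tests camera called 24, 14 up and 10 down, fry 54, and camera with an estimated correlation 0, with 16 under 0.05 before adjustment. Among miRNAs detected on all arrays, where fewer members remained, 12 calls were made, without the neuron list in neurons (adjusted p = 0.0578, median 2.76 in place of 3.79), the oligodendrocyte list in oligodendrocytes (0.136, 2.37 in place of 3.09) or the myeloid list in microglia (0.0705, 1.92 in place of 5.66). Also lost there were the myeloid list in neurons (0.4, -0.59 in place of -4.30, with 3 members left), the neuron list in microglia (0.0705, -2.42 in place of -3.43) and oligodendrocytes (0.162, 0.14 in place of 0.29), and the oligodendrocyte list in neurons (0.0705, -1.20 in place of -1.04). In microglia miR-30 (0.105, 0.71 in place of 0.87) and miR-23/27/24 (0.0939, median 1.20) were lost too. The Dlk1-Dio3 list kept 2 members under this filter, too few for a set test, with a median in oligodendrocytes of 0.43 in place of -1.20. Other sets not called were called under some alternatives. The miR-200 list in oligodendrocytes (adjusted p = 0.131, median -1.22) was called under quantile normalization (0.0366, -1.42), again against a mean that includes microglia. The astrocyte list in oligodendrocytes (adjusted p = 0.114, median -0.93) was called under normexp (0.00877), with no filter (0.0476) and without neuron arrays 1, 2 and 3 (0.0382, 0.0401 and 0.0392). The myeloid list in oligodendrocytes (0.295, median -0.92) was called under normexp (0.0167, -0.83) and in the deposited table (0.0403, -0.65), and the oligodendrocyte list in astrocytes (0.0602, median 0.70) with no filter (0.0468, 0.47) and without microglia array 2 (0.0287, 0.84). Median, mean and camera differed in sign in 7 of the tests, none of them called: the myeloid list and muscle in astrocytes, mesenchymal in neurons, let-7 in oligodendrocytes, and miR-15/16 in neurons, oligodendrocytes and microglia.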

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

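The tests of single explanations in this part were all chosen after the patterns were seen, except the comparison of scalings, and the random splits were chosen before. A stricter test of neuronal RNA was added when the first had not decided. The test of carry-over replaced an earlier one that did not bear on it, and the demand for at least 3 arrays in the test of brightness was set after its value was known.

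Astrocyte array 3 stood apart from the other astrocyte arrays in the noise of its negative control spots, whose SD was 141.7722 against 3.99 to 10.04 on the other 3. The gap was 0.956 of the range, over Dixon's limit for 4 arrays. This was 1 of 25 values tested (20 named miRNAs and 5 array measures), and chance singles out about 1 in 20. The array also had 7.54% outlier spots and 160 detected miRNAs. No biological explanation was tested.

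Neuron-associated and myeloid miRNAs were brighter on oligodendrocyte array 2 than on arrays 1 and 3. Lower total signal is argued against. The 16 listed miRNAs called higher in their own type and detected on an oligodendrocyte array rose by a median of 1.39. This was 1.32 above the median of 111 others of like brightness (0.07, SD 0.54). Those others were on neither list and not called higher in neurons or microglia. RNA from neurons like those profiled is argued against as the whole cause. Its share was bounded by the 36 Dlk1-Dio3 miRNAs called higher in neurons and not on the neuron list, which leaves out miR-494 and miR-136. The 10 of these brightest in neurons allow a median share of 1.97% (1.23 to 5.17). Of 12 neuron-associated miRNAs called higher in neurons, 7 need more, beyond the spread. Neuronal RNA stays open as a part, within the shares that the 10 brightest allow. All 36 together allow a median of 7.43% (quartiles 2.57 and 13.5) against a median of 7.16% needed. Many of the 36 lay at the floor on the oligodendrocyte arrays. There the floor over the neuron level sets the share, as for miR-543 (39.5%), so the closeness of these medians decides nothing. RNA from microglia, or another stage of the cells, may also contribute, and the stage was not tested. Undetected miR-150 allows 0.252% where 4 myeloid miRNAs need 2.94 to 6.0%. Of 9 undetected microglial miRNAs miR-150 alone lies below by more than the spread. For others, such as miR-200c (3.98%) and miR-141 (7.99%), the floor sets a share above the lowest needed. The count over the 9 therefore decides nothing, and the bound rests on miR-150 alone.

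The myeloid miRNAs miR-146a, miR-142-3p, miR-142-5p and miR-223 were measured on the astrocyte arrays at 5.94 to 7.38% of their microglial level. The other tested members of the myeloid list lay outside this range. miR-150 was at 0.84% and miR-146b at 47.1%, and miR-342-3p and miR-342-5p were 5.41-fold and 6.98-fold lower in astrocytes than in microglia. The range thus holds for these 4 and not for the list. RNA from microglia cannot be told apart from expression by astrocytes. Of 30 other miRNAs higher in microglia 4 lie below the needed level (miR-126, miR-130b, miR-150 and miR-200c), and 1 by more than the spread. The lowest, miR-150, allows 0.84%. Many of the 30 could not lie below, since their astrocyte signal was well above that level (miR-34a 49.7%, miR-16 41%) or the floor set it (miR-141 7.99%). The count therefore decides nothing, and the bound rests on miR-150 alone. Carry-over between arrays of slide 2 would move the same miRNAs and stays open as well, with the same 1 below by more than the spread. The overnight shaking of the astrocyte cultures was meant to remove microglia, and how many remained was not measured.

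More miRNAs were detected, and more called higher than lower, in neurons than in the other types. Slide 1 is argued against as the whole cause of the higher detection, since no oligodendrocyte array there detected more than 201. This compares detection alone, and a part played by the slide stays open. Brighter neuron arrays may contribute: astrocyte array 4, which detected 208 miRNAs, was the only array of another type brighter than a neuron array, and 1 array excludes nothing. Scaling stays open for the excess of higher over lower calls: it was 5 under quantile normalization (52 against 47), 50 against 37 with the 75th percentile over all miRNAs and 95 against 14 without scaling. Neuronal expression of the Dlk1-Dio3 domain may account for 37 of the 73 higher calls. Within slide 1 39 of 41 of its miRNAs were higher in neurons than in oligodendrocytes (camera, adjusted p = 7.48e-09, and 0.232 with an estimated correlation). Most of the 41 were tested only because the neuron arrays detected them.

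The arrays were also split at random into groups of the same sizes, 100 splits in all. The real split alone (1) reached the count of 256 miRNAs differing among types (highest other 108). The same held for higher (73, highest other 5) and lower (20, 2) in neurons and lower in astrocytes (8, 6). It held too for higher (13, 0) and lower (9, 0) in oligodendrocytes, and higher (34, 5) and lower (42, 5) in microglia. Chance is excluded for the grouping of the arrays as a whole, in which each type lay on 1 slide. Random splits mix cell types, which widens the spread within groups and lowers every count. They therefore decide nothing about a single type or miRNA. For higher in astrocytes 2 splits reached 9, and the other gave 41 with 3 neuron arrays and 1 astrocyte array in place of the astrocytes, which points to the structure of the samples. For the 24 list shifts, 10 splits gave as many (highest 29), so chance is not excluded. Among 35 splits of a pair, 1 reached the count for neurons and astrocytes (218, highest other 162), astrocytes and oligodendrocytes (151, 88) and astrocytes and microglia (176, 136). This excludes chance for the grouping of those arrays only, since the other splits mix the types and so lower the counts. In the first 2 of these pairs the types also lay on different slides. The 10 splits of 3 against 3 arrays are too few for a share under 0.05, with 209 (highest other 0) for neurons and oligodendrocytes, 223 (0) for neurons and microglia and 165 (1) for oligodendrocytes and microglia.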

How the results depend on the processing

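Leaving out oligodendrocyte array 2 with astrocyte array 3 was chosen after the data were seen. Of 430 counts under 14 alternatives and 13 arrays left out in turn, 393 stayed within 1.5 times and 37 did not; the cause was not tested except where named. Normexp gave 32 higher and 13 lower in neurons, 2 and 2 in astrocytes, 5 and 3 in oligodendrocytes, 21 and 15 in microglia, and 132, 133 and 81 for neurons against astrocytes, neurons against oligodendrocytes and astrocytes against oligodendrocytes. The 75th percentile over all miRNAs gave 37 lower in neurons and 2 in oligodendrocytes, and quantile normalization 47 lower in neurons. No scaling gave 21 higher in microglia and 100 for astrocytes against oligodendrocytes. The deposited table gave 43 higher in neurons, 5 lower in astrocytes and 3 lower in oligodendrocytes. A filter of detection on all arrays, which tests 119 miRNAs, gave 117 differing among types, 8 higher and 13 lower in neurons, 1 and 3 in astrocytes, 6 higher in oligodendrocytes, 16 and 18 in microglia, 101, 97, 100, 89, 97 and 90 for the 6 pairs (neurons against astrocytes, oligodendrocytes and microglia, astrocytes against oligodendrocytes and microglia, oligodendrocytes against microglia), and 12 list shifts. Leaving out a neuron array gave 33 (without array 3) to 39 (without array 2) higher in neurons, and 34 without array 1, since 37 of the 73 were then not tested. An estimated correlation gave 0 list shifts and fry 54. With the replicate number as a block the counts were 254 among types, 72 and 20, 9 and 8, 12 and 9, 34 and 42 per type in the same order, 202, 204, 221, 137, 169 and 161 per pair, and 24 list shifts, but the numbers do not pair the arrays: over 18 pairs of 1 number the median r of residuals was 0.000868, and 2 of 13 arrays matched their own number best. Without oligodendrocyte array 2 and astrocyte array 3 the counts were 256, 72 and 24, 9 and 6, 10 and 12, 32 and 41, then 211, 209, 232, 142, 183 and 161, and 23 list shifts. Of 3695 values of 146 named differences, 5 reversed: miR-134 in neurons (1.07) was -0.05 under quantile normalization and -0.12 in the deposited table, and miR-212 (-0.05, not past the threshold) was 0.51 without scaling, 0.01 without neuron array 3 and 0.02 without oligodendrocyte array 2. The slide as a block was not run, since it could not be fitted. Signal over background limits the dim miRNAs: 95 named values could not be tested when detection on all arrays was required.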

Other observations

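The values in this part were chosen after the data were seen. Several of these miRNAs were among the 268 tested, and no test was added for this part. Detected on every array of 1 type and on no other array were 39 miRNAs for neurons, 2 for astrocytes, 2 for microglia and 0 for oligodendrocytes. Detected on at least 1 array of 1 type alone were 45, 5, 6 and 1. miR-204, abundant in choroid plexus, was -0.24 ± 0.12 in neurons (n = 3) and -1.69 ± 0.04 in astrocytes (n = 4), against -5.21 ± 0.16 in oligodendrocytes and -7.13 ± 1.57 in microglia (n = 3 each). miR-135a was -0.70 ± 0.06 in astrocytes and -1.33 ± 0.02 in neurons, and was not detected in microglia. miR-342-3p, on the myeloid list, was -0.56 ± 0.03 in neurons, 0.28 ± 0.14 in microglia and -2.16 ± 0.05 in astrocytes. miR-451, known from red blood cells, was -4.64 ± 0.15 in neurons and -5.72 ± 0.57 in microglia, and was not detected in astrocytes or oligodendrocytes. miR-7b was -4.61 ± 0.01 in neurons and was detected on 1 array outside them.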
